A study of Rattus norvegicus with 16 samples.

How the data were processed

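RNA from the left ventricle of male Sprague Dawley rats was sequenced after 5/6 nephrectomy (5/6Nx), surgery that removes most of the kidney tissue, or after sham surgery. The labels give 4 times of collection (2, 4, 5 and 7 weeks after surgery) and 2 libraries per surgery and time, 16 in all. Each library was a pool of 2 to 3 rats. The libraries were made per the labels with a stranded total RNA kit and sequenced in pairs on an Illumina HiSeq. The hour of tissue collection was not given in the sources used here.

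The submitters' processing notes name cutadapt, TopHat2 2.0.10, Cufflinks 2.0.10, Cuffdiff and the rat genome build rn5, without roles or order. The 4 tables deposited by the authors, 1 per week, list 1 abundance per group and locus, taken here as the FPKM (fragments per kilobase of transcript, scaled to mega fragments) that Cuffdiff gives. The unit is not written in the file headers and was inferred from the named tool. Each week has its own table, and whether the weeks were scaled together was not given in the sources used here, so levels are compared within a week. The deposited test statistic is a score per locus, and the p-value and the q-value (the p-value adjusted over that week's tested loci) are the authors'. No value per library was in these tables. A further deposited table gives, per library, the count of reads sequenced, the percent of bases at quality 30 or above (Q30) and the percent of reads mapped. Its mean base quality and yield were read and not analysed here.

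A locus was called when the authors' deposited table marked it as significant. The planned design fitted limma or edgeR models only if the tables held a column per library. They did not, so the authors' own test stood and no model was fitted. Log2 fold changes (5/6Nx over sham) were computed from the deposited abundances, because the deposited fold-change column held entries that were not numbers. At week 7 the sign of the deposited test statistic was opposite to the fold change in all 13645 comparable loci. The deposited fold-change column of that week had the sign given by the columns named sham and 5/6Nx in all 13639 loci where both could be read. Directions were taken from these column names, and whether the names or the statistic are in the right order could not be settled from that table alone. Agreement with the fold changes of other weeks, given below, argues against exchanged names. Every direction at week 7 would turn if the names were exchanged. At week 7, 314 rows that repeated a locus under several symbols were joined, so that 253 called rows became 239 loci. Symbols that a spreadsheet had turned into dates (23 per table at weeks 2, 4 and 5, and 25 at week 7) were treated as unnamed. A standard error of each log2 fold change was derived as its size divided by the normal quantile of the deposited two-sided p. Where p was at its smallest deposited value, 5e-05, this standard error is an upper bound (0.247 times the log2 fold change). It measures the spread between pools as Cuffdiff modelled it, not between animals.

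Before the data were examined, 31 gene lists were fixed: 19 of functions and 12 of cell types. They held 588 different genes, of which 557 were matched to the tables by symbol. Older names were matched through a RefSeq gene table of a later rat assembly (GRCr8), used for symbols and synonyms and not for coordinates. Coordinates are those of the deposited tables in rn5. Where a symbol had several loci, the one with the highest mean FPKM represented it. For each list and week the median log2 fold change was compared with 10000 random lists of the same size, matched on mean FPKM in 20 bins. A list is described as above or below random lists when its median lay outside the central 95%. These percentiles describe these libraries, since genes are not replicates. Called and other genes in each list were also compared with the remaining tested genes by a two-sided Fisher's exact test, adjusted by the Benjamini-Hochberg method over 186 tests with a value (lists, weeks with calls and both directions). A count adjusted over the list alone used the deposited p-values of the list's tested genes.

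The named genes followed a rule fixed in advance. Per week they were the 10 named called genes with the largest rise and the 10 with the largest fall (FPKM of at least 1 in either group), and up to 4 called members of each list. To these were added 13 genes at every week (Nppa, Nppb, Myh6, Myh7, Acta1, Ppara, Col1a1, Col3a1, Postn, Timp1, Pdk4, Cpt1b and Atp2a2), genes called the same way in all 4 weeks or else in 3, and the 5 genes with the smallest adjusted p for a difference between weeks, 1 of which is not described here. Genes named outside this rule are marked as chosen after their values were seen.

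Overlaps of calls between weeks were tested with one-sided Fisher's exact tests, not matched on expression. These tests, like those of the lists, count genes as independent units. Genes measured in the same pools can change together, so the p-values do not measure a spread between pools or animals. Correlations of log2 fold changes between weeks were computed across loci, with no p-value. Differences of log2 fold change between weeks were tested with a z test on the derived standard errors, adjusted over all loci and 6 pairs of weeks. Mapping rates were compared between surgeries with an exact two-sided permutation test within weeks. The z test was tested on simulated data for 12755 loci of weeks 4 and 7, adjusted over that pair alone. In the simulation it recovered 13.4% of true differences of 1, 64.2% of those of 2 and 89.4% of those of 4 (log2). It made 8 calls among 12555 unchanged loci. With 6 pairs to adjust over, recovery in the test used can be lower. The noise was drawn from the derived standard errors, so the simulation cannot show whether those errors fit these pools. The list comparison placed 10 of 200 simulated unchanged lists (5%) and 50 of 50 lists shifted by 0.3 outside the central 95%.

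The alternatives tried were q thresholds of 0.01 and 0.10, adjustment over loci with an FPKM of at least 1, an absolute log2 fold change of at least 1, an FPKM filter, a pseudocount of 1, and fold changes centred on the median. Random lists without matching, an FPKM minimum of 10 and the removal of called loci from the correlations were also tried. Leaving out week 7, exchanging its column names, and leaving out each library for the mapping rate were added after the data were seen. The work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.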

Results

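The series followed the left ventricle of rats through the weeks after 5/6Nx, a surgical model of chronic kidney disease, to describe changes of heart gene expression at 2, 4, 5 and 7 weeks. Surgery was at 10 weeks of age. Each week had its own sham group, and each of the 8 groups held 2 libraries made from pools of 2 to 3 rats. The libraries held 44.5 to 61.8 M reads (M, mega), except pool 2 of the 5/6Nx group at week 7, which held 23.6 M. The 2 libraries of a 5/6Nx group together held 104, 108, 117 and 68.1 M reads at weeks 2, 4, 5 and 7. The sham groups held 107, 108, 109 and 101 M. The authors tested 14115, 14085, 13627 and 13665 loci at the 4 weeks. Values of single genes are group FPKM, without a spread between libraries in the tables, and log2 fold changes of 5/6Nx over sham ± the derived standard error.

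The first comparison asked what differed at week 2. Collagen, matrix remodelling, cell cycle and macrophage genes had fold changes mostly above 0, while no locus was called. The collagen and matrix list had a median log2 fold change of 0.36 with 25 of 28 tested genes above sham. The corresponding medians were 0.34 for matrix crosslinking and remodelling (16 of 20 genes), 0.44 for the cell cycle (17 of 19), 0.37 for macrophage and monocyte markers (19 of 20) and 0.20 for fibroblast markers (12 of 16). All 5 medians lay above random lists. Adjusted over the list alone, 13 matrix genes, 7 remodelling genes, 4 macrophage genes, 4 fibroblast genes and 0 cell cycle genes were higher, against 0 of each over all genes.

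Among the genes fixed in advance, the fibrillar collagen genes Col3a1 (XLOC_021450, chromosome 9, 51689491 to 51725418) and Col1a1 (XLOC_003706, chromosome 10, 82563433 to 82580364) had log2 fold changes of 0.77 ± 0.19 and 0.66 ± 0.17. Col3a1 had 296 to 504 FPKM in sham and 5/6Nx. Values were 0.54 ± 0.18 for Postn, which encodes periostin, a matrix protein of activated fibroblasts, and 0.73 ± 0.21 for Timp1, an inhibitor of matrix metalloproteinases. The natriuretic peptide genes Nppa and Nppb stood at 0.35 ± 0.18 and 0.64 ± 0.18. Values of the other fixed genes were 0.01 ± 0.17 for Acta1, -0.07 ± 0.29 for Ppara, -0.24 ± 0.19 for Pdk4, 0.05 ± 0.17 for Cpt1b and -0.11 ± 0.22 for Atp2a2. In the authors' deposited table the q-values of Col3a1 and Col1a1 were 0.0504 and 0.0784. With the immediate early genes, which respond first to stimuli, 19 of 25 were above sham and the median was 0.17, above random lists, with 5 higher and 1 lower adjusted over the list alone and 0 over all genes. Red cell markers were also above random lists, with a median of 0.28.

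By Cuffdiff, 0 of 14115 tested loci were called at week 2 in the authors' deposited table, where 391 had an unadjusted p under 0.05 (260 higher, 131 lower). That is 2.77% of the tested loci, below the 5% expected of uniform p-values with no change, so the count alone is no evidence of a change. The smallest q in the authors' deposited table was 0.0504, shared by 14 loci at the smallest deposited p, 5e-05. Adjusted over loci with an FPKM of at least 1, all 14 passed with an adjusted p of 0.0479 (11 higher, 3 lower). Named here after their values were seen, they included Reg3b (2.53 ± 0.62), Alox15, a lipoxygenase (1.80 ± 0.44), Loxl1, a collagen and elastin crosslinking enzyme (1.00 ± 0.25), Col3a1, and, below sham, S100a9, which encodes a calprotectin subunit of myeloid cells (-1.62 ± 0.40).

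At week 4, 47 loci were called, 25 higher and 22 lower. Matrix and cell cycle genes rose and adipocyte, immediate early and some atrial genes fell. Postn (XLOC_011096, chromosome 2, 163331223 to 163362445) rose 1.88-fold, from 11.5 to 21.6 FPKM (0.91 ± 0.22). Adipoq (XLOC_005416, chromosome 11, 84363754 to 84382663), which encodes the adipocyte hormone adiponectin, fell from 9.34 to 3.41 FPKM (-1.46 ± 0.36). Cdk1, the kinase that drives entry into mitosis, rose from 3.34 to 7.68 FPKM (1.2 ± 0.30).

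Of 29 tested collagen and matrix genes at week 4, 6 rose, 0 fell and 23 did not pass, with 15 higher and 1 lower adjusted over the list alone. They were Postn, Fbn1 (0.90 ± 0.22), which encodes the microfibril protein fibrillin-1, Col8a1 (0.82 ± 0.20), Cilp (0.79 ± 0.19), Col3a1 (0.71 ± 0.17) and Col1a1 (0.69 ± 0.17). The list's median was 0.35, and calls were enriched (Fisher's exact test, adjusted p = 8.90e-10). Of 16 fibroblast markers, Postn and Col1a1 rose, both also in the matrix list (median 0.25, 5 higher and 0 lower adjusted over the list alone, adjusted p = 0.00569 by Fisher's exact test). Cdk1 and Top2a, a topoisomerase of dividing cells (1.10 ± 0.27), rose among 19 cell cycle genes, with 9 higher and 0 lower adjusted over the list alone. That list's median was 0.83 (Fisher's exact test, adjusted p = 0.00713). Prc1, a spindle protein of cell division, also rose (1.04 ± 0.26). Sele, the endothelial adhesion molecule E-selectin, rose (1.37 ± 0.34), the 1 called gene of 24 cytokine and inflammation genes (median 0.36, 2 higher and 0 lower adjusted over the list alone). Aplnr, the apelin receptor, rose (0.70 ± 0.17), the 1 called gene of 19 in the angiogenesis list (median 0.14, 1 higher and 0 lower adjusted over the list alone).

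No gene of 19 in the remodelling list was called at week 4 (median 0.20, 7 higher and 1 lower adjusted over the list alone). Other large rises at week 4 were those of Fam111a (1.13 ± 0.28), Arhgap20 (1.01 ± 0.25) and Slc37a2 (0.89 ± 0.24). Another was at the locus of the microRNA genes Mir199a and Mir214 (4.53 ± 1.12), which spans 475.94 kb (XLOC_006382, chromosome 13, 84796112 to 85272051). That single locus covers far more sequence than the 2 microRNA genes, and its call turned direction at week 5.

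Of 10 tested adipocyte markers at week 4, 5 fell, 0 rose and 5 did not pass, with 0 higher and 6 lower adjusted over the list alone. All 10 lay below sham, and the median was -1.33 (Fisher's exact test, adjusted p = 5.27e-10). Besides Adipoq these were the lipid droplet genes Cidec (-2.25 ± 0.56) and Plin1 (-1.85 ± 0.46), Thrsp, a regulator of lipid synthesis (-1.44 ± 0.35), and Pck1, which encodes phosphoenolpyruvate carboxykinase (-1.36 ± 0.34). Of 25 immediate early genes, 3 fell, with 0 higher and 7 lower adjusted over the list alone: Atf3 (-1.41 ± 0.35), Cyr61 (-0.96 ± 0.24) and Fos (-0.83 ± 0.21). The list's median was -0.19 (Fisher's exact test, adjusted p = 2.12e-04). Among 14 atrial, valve and conduction markers, Sln, an inhibitor of the calcium pump (-0.93 ± 0.23), and Myl7, the atrial regulatory light chain (-0.83 ± 0.21), fell, with 1 higher and 4 lower adjusted over the list alone. The median was -0.40 (Fisher's exact test, adjusted p = 0.00420).

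Further falls at week 4 were those of Car3, a carbonic anhydrase (-1.34 ± 0.33), Abra (-1.0 ± 0.25) and Wfdc1 (-0.94 ± 0.23). Pdk4, the kinase that inhibits pyruvate dehydrogenase, fell from 467 to 282 FPKM (-0.73 ± 0.18) and was the 1 called gene of 18 PPAR-alpha targets. That list had a median of -0.21 with 17 genes below sham (0 higher and 1 lower adjusted over the list alone). All 23 tested genes of fatty acid uptake and oxidation lay below sham, with a median of -0.22 and no call (0 higher and 0 lower adjusted over the list alone). Values of fixed genes that were not called were 0.44 ± 0.16 for Nppa, 0.11 ± 0.15 for Nppb and 0.46 ± 0.18 for Timp1. Acta1, Ppara, Cpt1b and Atp2a2 stood at -0.02 ± 0.15, 0.02 ± 0.28, -0.11 ± 0.15 and -0.17 ± 0.20. Of the 47 calls, 21 had a fold change of at least 2 (an absolute log2 fold change of at least 1). In the authors' deposited table the smallest q at this week was 0.0185, so 0 loci passed at 0.01, and 75 passed at 0.10. Rps6, named after its values were seen, was called and listed at 0 in 1 group, so it has no fold.

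At week 5, 75 loci were called, 54 higher and 21 lower. Nppa, which encodes atrial natriuretic peptide and rises in the loaded ventricle (XLOC_016743, chromosome 5, 168466308 to 168467618), rose 2.12-fold, from 855 to 1810.3 FPKM (1.08 ± 0.27). Cell cycle, matrix and red cell genes rose, adipocyte genes fell, and clock genes changed in both directions. Postn rose from 5.45 to 13.6 FPKM (1.32 ± 0.33), and Thrsp fell from 40.5 to 2.19 FPKM (-4.21 ± 1.04).

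Of 20 cell cycle genes at week 5, 5 rose, 0 fell and 15 did not pass, with 12 higher and 0 lower adjusted over the list alone. All 20 lay above sham, with a median of 1.16 (Fisher's exact test, adjusted p = 5.21e-07). Called genes included Cdk1 (1.69 ± 0.42), Top2a (1.64 ± 0.40), Rrm2, a ribonucleotide reductase subunit (1.35 ± 0.33), and Tpx2, a spindle assembly factor (1.34 ± 0.35). Rises of division genes outside the list were 1.92 ± 0.47 for Prc1, 1.88 ± 0.48 for Cdca3, 1.81 ± 0.45 for the kinesin gene Kif23, 1.64 ± 0.40 for Cdkn3 and 1.63 ± 0.40 for Ube2c, a ubiquitin ligase factor of mitotic exit. Arsi, an arylsulfatase gene, rose from 0.3 to 1.75 FPKM (2.55 ± 0.65), and Fam64a also rose (1.78 ± 0.44).

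Of 28 collagen and matrix genes at week 5, 6 rose, 0 fell and 22 did not pass, with 15 higher and 0 lower adjusted over the list alone. The median was 0.45 (Fisher's exact test, adjusted p = 7.47e-08). Besides Postn, called genes included Comp (1.26 ± 0.32), Eln, which encodes elastin (1.08 ± 0.27), and Ltbp2 (1.04 ± 0.26). Postn and Thy1 (1.29 ± 0.32) rose among 16 fibroblast markers (median 0.31, 5 higher and 0 lower adjusted over the list alone, adjusted p = 0.0195 by Fisher's exact test). Loxl1 rose (0.95 ± 0.23), the 1 called gene of 19 in the remodelling list, where every tested gene lay above sham (median 0.29, 5 higher and 0 lower adjusted over the list alone). Fold changes of the fixed collagen genes were 0.71 ± 0.20 for Col1a1 and 0.73 ± 0.23 for Col3a1, not called.

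Of 7 red cell loci at week 5, 4 rose, with 4 higher and 0 lower adjusted over the list alone and a median of 1.00 (Fisher's exact test, adjusted p = 3.14e-07). They were the beta-globin locus listed as Hbb,LOC100134871,LOC689064 (1.16 ± 0.29), from 3088 to 6881 FPKM, the alpha-globin loci LOC287167,LOC360504 (1.00 ± 0.25) and Hba-a2 (0.86 ± 0.22), and Alas2, the haem synthesis enzyme of red cells (1.34 ± 0.33). Reads shared between globin paralogs were not separated here. Ccl2, a monocyte chemokine (0.95 ± 0.23), and S100a9 (1.71 ± 0.42) rose among 22 cytokine and inflammation genes (median 0.23, 4 higher and 0 lower adjusted over the list alone, adjusted p = 0.0354 by Fisher's exact test). S100a9 was also the 1 called gene of 6 neutrophil and mast cell markers (median 0.18, 2 higher and 0 lower adjusted over the list alone). The macrophage gene Lyz2, which encodes lysozyme, rose (0.67 ± 0.18), the 1 called gene of 20 macrophage markers (median 0.34, 1 higher and 0 lower adjusted over the list alone). Cdkn1a, a cell cycle inhibitor gene, rose (0.96 ± 0.24), the 1 called gene of 17 in the glucocorticoid and mineralocorticoid list. That list's median was -0.14 and its mean 0.03, with 1 higher and 0 lower adjusted over the list alone.

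Of 14 circadian clock and clock output genes at week 5, 2 rose, 4 fell and 8 did not pass, with 2 higher and 7 lower adjusted over the list alone. Arntl, which encodes the clock activator BMAL1 (1.56 ± 0.39), rose. Falls were those of RGD1566380, the symbol matched to Ciart (-1.66 ± 0.41), Dbp (-1.16 ± 0.29) and Per3 (-1.02 ± 0.25), which lie downstream of that activator. Named after their values were seen, the other two were Npas2, which rose (0.91 ± 0.24), and Tef, which fell (-0.73 ± 0.18). Calls were enriched for rises (adjusted p = 0.0162) and falls (adjusted p = 3.10e-07) by Fisher's exact test, and the median was -0.37. The hour of collection was not given in the sources used here.

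Adipocyte markers were again lower at week 5: 5 of 10 fell, 0 rose and 5 did not pass, with 0 higher and 6 lower adjusted over the list alone. All 10 lay below sham, and the median was -2.33 (Fisher's exact test, adjusted p = 5.27e-10). Falls were -4.32 ± 1.06 for Pck1, -3.01 ± 0.74 for Cidec, -2.84 ± 0.70 for Plin1 and -1.81 ± 0.45 for Adipoq. Ucp1, the uncoupling protein gene of brown fat, named after its values were seen, went from 30.2 to 0.0361 FPKM and was not called (-9.71 ± 8.38). Fasn and Scd1, enzymes of fatty acid synthesis and desaturation, fell alongside (-2.19 ± 0.54 and -1.90 ± 0.47), as did Rbp4, the retinol carrier gene (-1.69 ± 0.42). The microRNA locus fell (-4.83 ± 1.19). Atp5f1 fell (-2.28 ± 0.59) at 1 of 3 loci with that symbol and was the 1 called gene of 38 for oxidative phosphorylation.

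Among 14 atrial, valve and conduction markers at week 5, the 2 called genes were Nppa and Comp, which stand also in the natriuretic and matrix lists. Their calls were enriched (Fisher's exact test, adjusted p = 0.0162), while the list's median was 0.07 and its mean -0.06 (2 higher and 1 lower adjusted over the list alone). Nppa was the 1 called gene of 12 natriuretic peptide and hypertrophy genes (median 0.25, 1 higher and 0 lower adjusted over the list alone). Values not called were 0.36 ± 0.18 for Nppb, 0.68 ± 0.21 for Timp1, 0.60 ± 0.23 for Pdk4 and 0.39 ± 0.25 for Acta1, the skeletal actin gene of the fetal heart. Ppara, Cpt1b and Atp2a2 stood at -0.05 ± 0.50, -0.19 ± 0.19 and -0.11 ± 0.34. In the authors' deposited table the smallest q at week 5 was 0.0114, so 0 loci passed at 0.01. Among the calls, 2 were listed at 0 in 1 group and have no fold, Aspg (named after its values were seen) and an unnamed locus.

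At week 7, 239 loci were called, 196 higher and 43 lower. Matrix, macrophage, inflammatory and immediate early genes rose, and Acads and Mlycd of fatty acid oxidation and Myl7 and Bmp10 of the atrium fell. Spp1, which encodes the matrix and cytokine-like protein osteopontin (XLOC_007264, chromosome 14, 6653083 to 6659006), rose from 10.6 to 234 FPKM (4.46 ± 1.10). Nppa rose 5.49-fold, from 613 to 3362 FPKM (2.46 ± 0.61). Postn rose from 18.3 to 205 FPKM (3.49 ± 0.86), and Timp1 (XLOC_022438, chromosome X, 2136357 to 2193641) from 16.7 to 116 FPKM (2.80 ± 0.69). These directions rest on the column names of the week 7 table, whose test statistic has the opposite sign, and all of them (196 higher, 43 lower) would turn if the names were exchanged. Under the names as given, log2 fold changes at week 7 correlated positively with those of weeks 2, 4 and 5 (Pearson's r across loci 0.25, 0.31 and 0.30), and with the names exchanged these values would be negative.

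Of 29 collagen and matrix genes at week 7, 10 rose, 0 fell and 19 did not pass, with 13 higher and 0 lower adjusted over the list alone. The median was 0.59 (Fisher's exact test, adjusted p = 2.04e-09). Called genes included Ltbp2 (2.81 ± 0.69), Tnc, which encodes tenascin-C (2.61 ± 0.64), and Col8a1 (2.38 ± 0.59). Of 20 genes of matrix crosslinking and remodelling, 8 rose, with 10 higher and 0 lower adjusted over the list alone and a median of 0.77 (Fisher's exact test, adjusted p = 3.21e-08). Besides Spp1 and Timp1 these included Lox, which crosslinks collagen (3.43 ± 0.85), and Ctgf, a growth factor of the fibrotic response (1.85 ± 0.46). Postn and Mfap5 (1.32 ± 0.32) rose among 16 fibroblast markers (median 0.34, 6 higher and 0 lower adjusted over the list alone, adjusted p = 0.211 by Fisher's exact test). The fixed collagen genes were not called, at 0.64 ± 0.27 for Col1a1 and 0.93 ± 0.31 for Col3a1.

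Of 19 macrophage and monocyte markers at week 7, 8 rose, 0 fell and 11 did not pass, with 18 higher and 0 lower adjusted over the list alone. The median was 1.18 (Fisher's exact test, adjusted p = 2.34e-08). Examples were Lyz2 (2.36 ± 0.58), Cd68 (2.19 ± 0.54), Lgals3, which encodes galectin-3 (1.82 ± 0.45), and Itgam, an integrin of myeloid cells (1.82 ± 0.45). Of 25 cytokine and inflammation genes, 5 rose, with 13 higher and 0 lower adjusted over the list alone and a median of 0.97 (Fisher's exact test, adjusted p = 0.00104). Called genes included the chemokines Ccl2 (2.80 ± 0.69) and Ccl7 (2.09 ± 0.52), Sele (2.79 ± 0.69) and Ptgs2, the inducible cyclooxygenase gene (2.44 ± 0.60). Olr1, a scavenger receptor gene, rose (3.90 ± 0.96), as did Alox15 (3.85 ± 0.95), Rgs1 (3.30 ± 0.81), Trh (3.14 ± 0.78) and Tnfrsf11b, which encodes osteoprotegerin (2.90 ± 0.72).

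Of 25 immediate early genes at week 7, 4 rose, with 11 higher and 0 lower adjusted over the list alone: Egr2 (2.44 ± 0.60), Egr3 (1.80 ± 0.44), Egr1 (1.14 ± 0.29) and Klf4 (0.97 ± 0.28). All 25 lay above sham, with a median of 0.68 (Fisher's exact test, adjusted p = 0.00956). The metallothionein genes Mt2A (3.77 ± 0.93) and Mt1a (3.04 ± 0.75), whose products bind metals, stand in both the corticosteroid and the oxidative stress list. With them, Serpina3n (2.18 ± 0.65) and Hsd11b1, which regenerates active glucocorticoid (1.19 ± 0.29), were among 6 of 18 corticosteroid-responsive genes that rose. That list's median was 0.28 (7 higher and 0 lower adjusted over the list alone, adjusted p = 8.50e-06 by Fisher's exact test). Of 22 oxidative stress genes, 4 rose (median 0.32, 5 higher and 0 lower adjusted over the list alone, adjusted p = 0.00685 by Fisher's exact test). Besides the metallothioneins they were Hmox1, which encodes haem oxygenase (1.53 ± 0.38), and Cybb, the oxidase subunit of phagocytes (1.53 ± 0.38).

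Falls at week 7 included genes of fuel use. Mlycd (-1.13 ± 0.30, at 1 of 2 loci) and Acads, an acyl-CoA dehydrogenase gene (-1.11 ± 0.33), fell among 23 genes of fatty acid uptake and oxidation. That list had 20 genes below sham and a median of -0.54 (0 higher and 8 lower adjusted over the list alone, adjusted p = 0.0167 by Fisher's exact test). Ucp3, a mitochondrial carrier gene (-1.61 ± 0.47), and Aqp7, a glycerol channel gene (-1.06 ± 0.30), fell among 18 PPAR-alpha targets (median -0.51, 0 higher and 3 lower adjusted over the list alone, adjusted p = 0.0117 by Fisher's exact test). Eno3, the muscle enolase gene, fell (-1.33 ± 0.33), the 1 called gene of 22 for glycolysis (1 higher and 4 lower adjusted over the list alone). Bmp10 (-1.73 ± 0.43) and Myl7 (-1.31 ± 0.32) fell and Nppa rose among 14 atrial, valve and conduction markers. That list's median was -0.43 (1 higher and 3 lower adjusted over the list alone), with falls enriched (Fisher's exact test, adjusted p = 0.00782).

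Pdia2, a protein disulfide isomerase gene, fell at week 7 (-2.94 ± 0.84). Further falls were those of the glucagon receptor gene Gcgr (-1.84 ± 0.52), Gpt, an alanine aminotransferase gene (-1.81 ± 0.49), Scgn (-1.65 ± 0.42, at 1 of 2 loci), Pyroxd2 (-1.55 ± 0.42), Ros1 (-1.55 ± 0.38), Tmod4 (-1.39 ± 0.39) and Ky (-1.38 ± 0.34). Single called genes of other lists were Angpt1, an angiopoietin gene (-1.22 ± 0.30), Bst2, an interferon-stimulated gene (-1.12 ± 0.33), and the muscle creatine kinase gene Ckm (-0.95 ± 0.28), which fell. Ncam1 (1.53 ± 0.38) and the clock gene Bhlhe40 (0.97 ± 0.27) rose. Alas2 (1.28 ± 0.34) and Hba-a2 (1.11 ± 0.27) rose among 9 red cell markers, whose median was 0.83 (5 higher and 0 lower adjusted over the list alone, adjusted p = 0.0773 by Fisher's exact test). Top2a rose (1.10 ± 0.32), the 1 called gene of 14 cell cycle genes (median 1.09, 6 higher and 0 lower adjusted over the list alone). Adipocyte markers had a median of -0.85 over 5 tested genes, none called (0 higher and 2 lower adjusted over the list alone).

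Values not called at week 7 were 0.85 ± 0.26 for Nppb, -0.54 ± 0.26 for the calcium pump gene Atp2a2, -0.67 ± 0.40 for Ppara, -0.61 ± 0.27 for Cpt1b, -0.43 ± 0.33 for Pdk4 and -0.18 ± 0.28 for Acta1. The myosin heavy chain genes Myh6 and Myh7 share 1 locus in the tables (XLOC_008069, chromosome 15, 37492064 to 37544303), so a shift between them cannot be read. That locus stood at -0.19 ± 0.22, -0.22 ± 0.22, -0.14 ± 0.53 and -1.04 ± 0.53 at weeks 2, 4, 5 and 7 and was not called. At week 7, 137 of the 239 loci passed at a q of 0.01 in the authors' deposited table. The 5/6Nx group of week 7 had the lowest depth and the log2 fold changes the widest spread. The SD over tested loci with an FPKM of at least 1 in either group was 0.63. At weeks 2, 4 and 5 it was 0.31, 0.30 and 0.36. At week 7, 5 called loci, among them Gal (named after its values were seen), were listed at 0 in 1 group and have no fold.

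**Figure D1:**
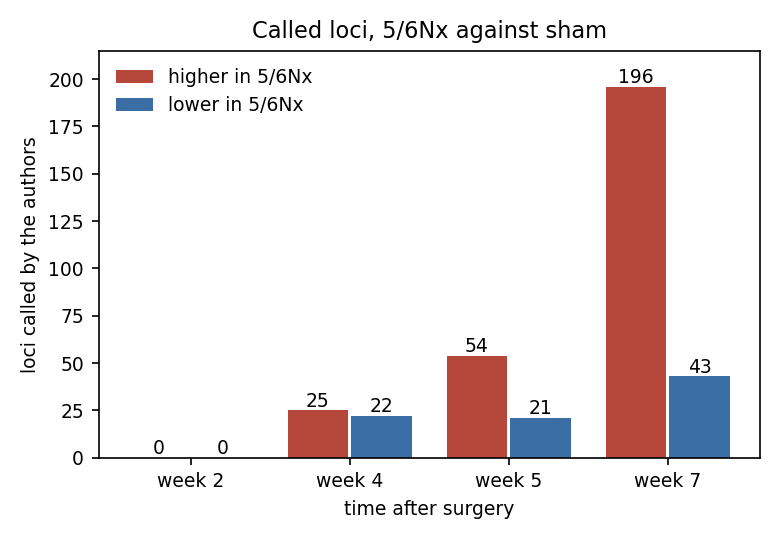
Number of loci called as higher (red) or lower (blue) in 5/6Nx than in sham, by week after surgery, in the authors' deposited tables. Calls numbered 0, 47, 75 and 239 at weeks 2, 4, 5 and 7.

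The lists with few calls or none were compared over the 4 weeks by their medians, given here in the order of weeks 2, 4, 5 and 7. Oxidative phosphorylation had medians of -0.16, -0.18, -0.03 and -0.24, below random lists at each week, with 36, 37, 24 and 34 genes below sham. Calcium handling and ion channels had -0.10, -0.16, -0.18 and -0.38 and sarcomere structure -0.12, -0.19, -0.07 and -0.31, both below random lists at weeks 4, 5 and 7, with no call. Fatty acid uptake and oxidation had -0.11, -0.22, -0.14 and -0.54 and PPAR-alpha targets -0.02, -0.21, -0.10 and -0.51. Both lay below random lists at weeks 4, 5 and 7. They share Cpt1a, Cpt1b, Fabp3 and Slc25a20, so they are not separate evidence. Glycolysis had -0.01, -0.09, -0.01 and -0.14. The natriuretic peptide list had -0.03, -0.02, 0.25 and 0.23, above random lists at week 5. The renin-angiotensin and endothelin list had -0.03, 0.14, 0.15 and 0.35, above at week 7. The unfolded protein response had 0.13, -0.08, 0.09 and -0.23, above at weeks 2 and 5 and below at week 7. Interferon-stimulated genes had -0.02, 0.15, 0.15 and -0.13, above at weeks 4 and 5. Angiogenesis and hypoxia had 0.03, 0.14, 0.01 and 0.22, above at week 4. Oxidative stress genes had 0.02, -0.03, 0.04 and 0.32, above at week 7, and corticosteroid-responsive genes -0.08, -0.12, -0.14 and 0.28, below at week 5 and above at week 7. Clock genes had -0.13, -0.01, -0.37 and -0.13, below at weeks 2 and 5. Immediate early genes had 0.17, -0.19, 0.05 and 0.68, above at weeks 2 and 7 and below at week 4. The cytokine list had 0.08, 0.36, 0.23 and 0.97, above at every week, as were the matrix, remodelling, cell cycle and fibroblast lists.

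Among markers of other cells, endothelial genes had medians of 0.06, 0.14, 0.11 and 0.05, above random lists at weeks 2, 4 and 5, and smooth muscle and pericyte genes 0.10, 0.03, 0.07 and 0.00, above at week 2. Macrophage markers had 0.37, 0.30, 0.34 and 1.18 and red cell markers 0.28, 0.19, 1.00 and 0.83, each above random lists at every week. Lymphocyte markers had -0.23, -0.05, 0.02 and -0.37, below at week 2. Neutrophil and mast cell markers had 0.06, 0.24, 0.18 and 0.00, above at week 4. Nerve markers had 0.02, 0.13, 0.01 and 0.15, within random lists at every week, and mesothelial markers 0.13, 0.23, 0.38 and 0.39, above at week 5. Skeletal muscle markers had -0.20, -0.35, -0.04 and -0.13 and atrial markers -0.15, -0.40, 0.07 and -0.43, the first below at weeks 2 and 4 and the second at weeks 2, 4 and 7. Adipocyte markers had -0.31, -1.33, -2.33 and -0.85, below at every week. With random lists drawn without matching, the medians of oxidative phosphorylation, sarcomere, unfolded protein and endothelial genes at week 5 and of endothelial genes at week 2 lay within the central 95%. So did the cytokine list at week 2 with a pseudocount of 1 (0.04), and the atrial and skeletal muscle lists at week 2 with an FPKM of at least 1.

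In lists without a call, the counts adjusted over the list alone were as follows, besides those given above. At week 2 they were 1 higher for natriuretic, PPAR-alpha and clock genes each, 2 higher and 3 lower for cytokines, 2 lower for neutrophil and mast cell markers and 1 lower for adipocyte markers. At week 4 they were 2 higher and 1 lower for clock genes, 1 of each for red cell markers, 1 higher for mesothelial markers, and 1 lower for glycolysis, calcium handling and smooth muscle genes each. At week 7 they were 2 lower for calcium handling and 1 higher for the renin-angiotensin list. The remaining lists without a call had 0 adjusted over the list alone, against 0 over all genes. Medians and means had opposite signs in 15 of the combinations of list and week. Of these, the medians of cytokines (mean -0.07) and clock genes (mean 0.00) at week 2 and of corticosteroid-responsive genes at week 5 lay outside the central 95%. The others were the natriuretic list at weeks 2 and 4, the clock list at weeks 4 and 7, neutrophil and mast cell markers at weeks 2 and 7, PPAR-alpha targets and interferon-stimulated genes at week 2, oxidative stress genes at week 4, and glycolysis, atrial and skeletal muscle genes at week 5.

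**Figure D2:**
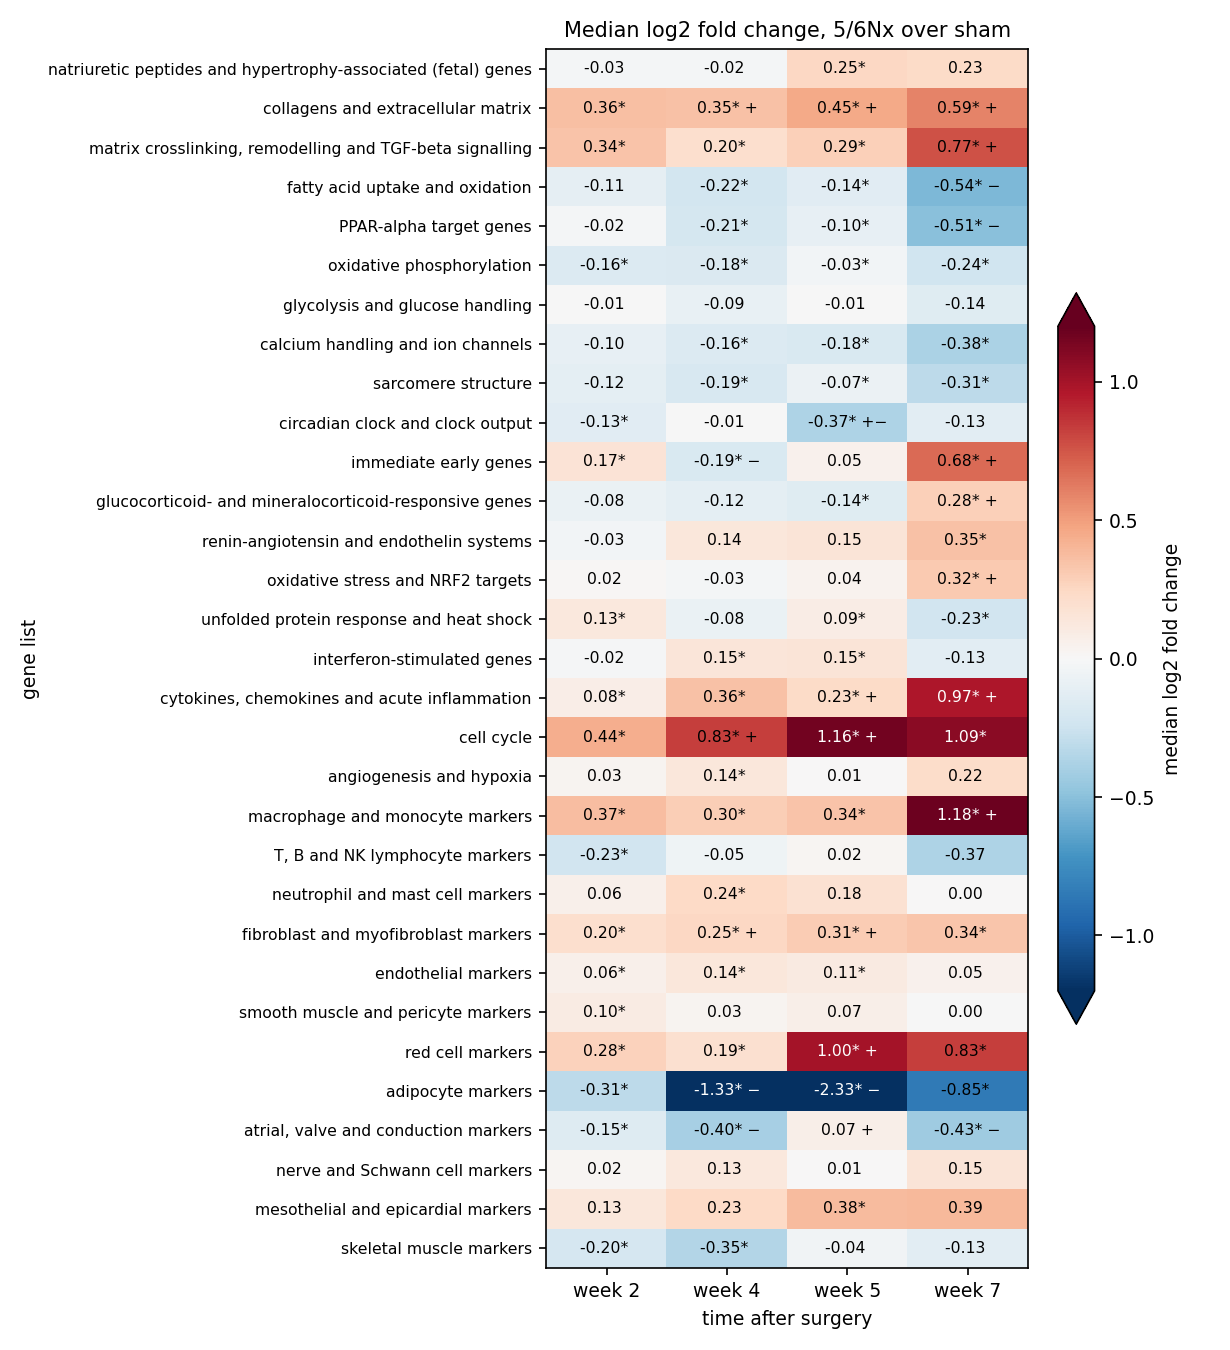
Median log2 fold change (5/6Nx over sham) of the 31 gene lists at each week, by colour, which ends at 1.2 in either direction, and printed. An asterisk marks medians outside the central 95% of matched random lists, and + or − marks lists enriched for calls higher or lower; adipocyte markers reached -2.33 at week 5 and macrophage markers 1.18 at week 7.

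The next comparison asked which genes moved again at another week. Over all weeks 327 loci were called, of which 29 were called in the same direction in at least 2 weeks (22 higher, 7 lower). Postn, Fbn1, Prc1 and Top2a rose at weeks 4, 5 and 7, and no locus was called at all 4. At week 2 the test of Fbn1 failed in the authors' deposited table, where it was listed at 19.9 FPKM in sham and at 0 in 5/6Nx. Fbn1 had log2 fold changes of 0.90 ± 0.22, 0.74 ± 0.18 and 1.48 ± 0.36, and Prc1 1.04 ± 0.26, 1.92 ± 0.47 and 1.40 ± 0.37. Weeks 5 and 7 shared 18 rises, among them Nppa, Ccl2, Ltbp2, Alas2 and Lyz2, where 0.692 would be shared by independent lists (one-sided Fisher's exact test, adjusted p = 9.01e-21). Weeks 4 and 5 shared 6 rises (0.0887 by independence, adjusted p = 4.55e-10) and 6 falls (0.0303, adjusted p = 6.08e-13). The shared falls were Cidec, Plin1, Adipoq, Thrsp, Pck1 and Car3. Weeks 4 and 7 shared 6 rises (0.374, adjusted p = 2.17e-06) and 1 fall, Myl7 (0.0546, adjusted p = 0.0639). Weeks 5 and 7 shared 0 falls (0.0423, adjusted p = 1). If the column names of week 7 were exchanged, a case chosen after the data were seen, week 7 would share 0 rises and 0 falls with weeks 4 and 5. The 21 loci that it shares with either week (20 higher, 1 lower) would then be called in opposite directions, and the 12 loci shared by weeks 4 and 5 would remain. No controls were shared between weeks, and the overlap tests count loci as independent units, which they are not. Without week 7, 12 loci were called in the same direction in at least 2 weeks, and at a q of 0.01 there were 0.

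**Figure D3:**
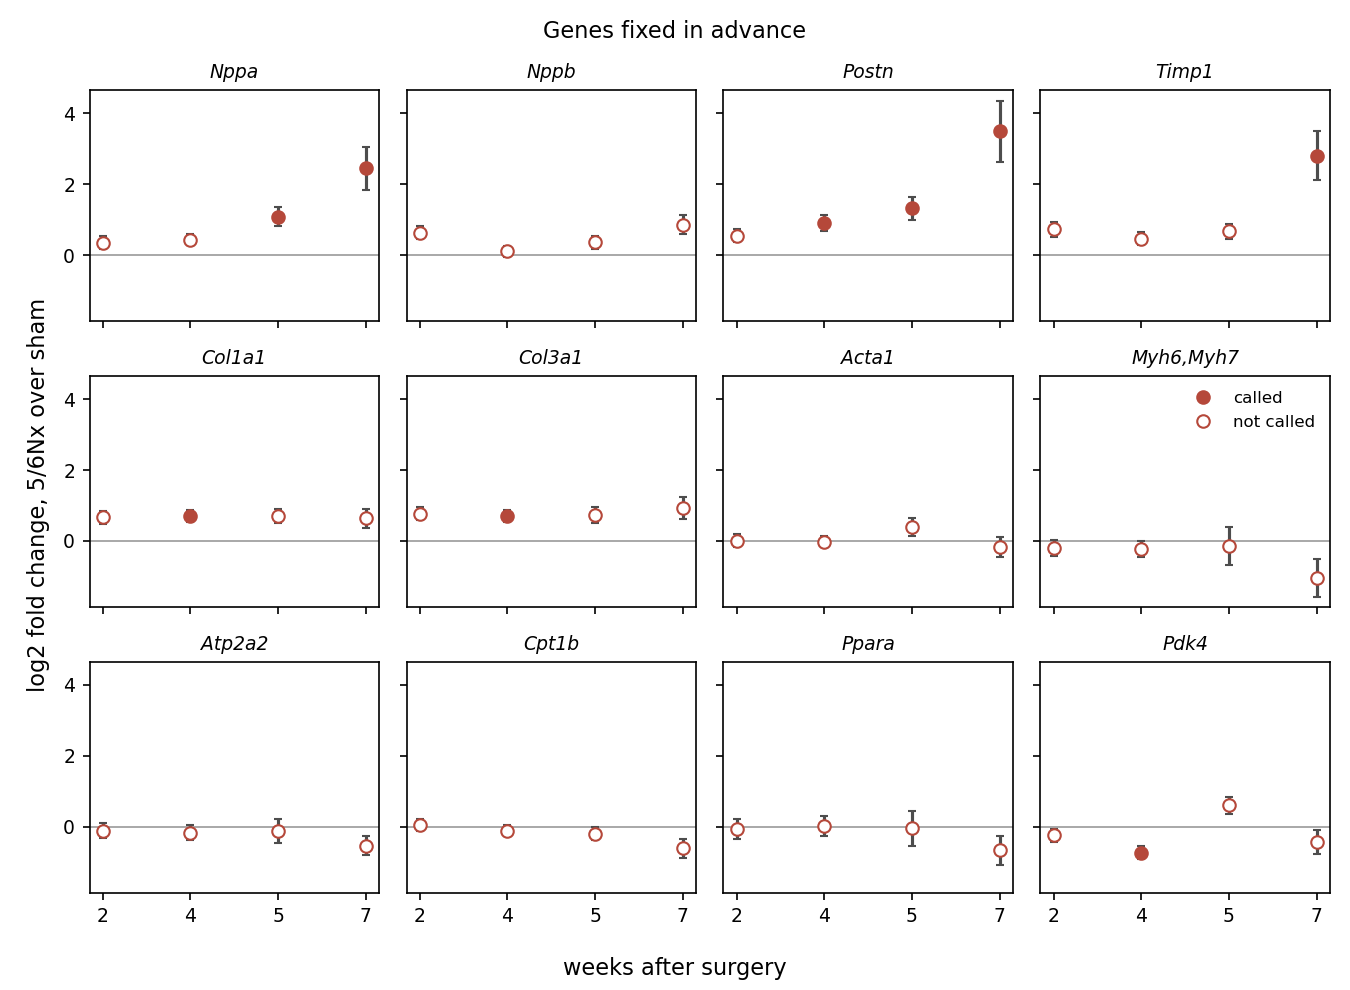
Log2 fold change (5/6Nx over sham) of the genes fixed in advance, against weeks after surgery. Points are filled where the authors' deposited table called the locus, and bars are the derived standard error (at week 7, 3.49 for Postn and 2.46 for Nppa, or -3.49 and -2.46 if the column names of that week were exchanged).

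Across loci, log2 fold changes of different weeks were weakly and positively related. Pearson's r was 0.25 for weeks 2 and 4, 0.22 for 2 and 5, 0.25 for 2 and 7, 0.25 for 4 and 5, 0.31 for 4 and 7 and 0.30 for 5 and 7. With no FPKM minimum and a pseudocount of 1, that of weeks 2 and 5 was 0.106, and the cause was not tested. Spearman's rho was 0.32, 0.26, 0.21, 0.25, 0.33 and 0.32 in the same order, over 11709 to 12885 loci with an FPKM of at least 1. Between 56.1% and 62.7% of loci had the same sign. These correlations are across genes, which are not independent replicates, so no p-value is given.

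The difference of fold change between weeks was tested directly. S100a9 was below sham at week 2 (-1.62 ± 0.40) and above it at week 5 (1.71 ± 0.42), a difference of 3.33 ± 0.58 (adjusted p = 3.85e-04). Cebpa, a transcription factor gene of myeloid and fat cells, went from -0.98 ± 0.29 at week 5 to 1.90 ± 0.52 at week 7 (adjusted p = 0.0258). Lyc2, a lysozyme gene, went from -1.74 ± 0.51 at week 5 to 2.09 ± 0.57 at week 7 (z test, adjusted p = 0.0157). Both genes had low levels. Sham and 5/6Nx FPKM of Cebpa were 2.93 and 1.49 at week 5 and 0.754 and 2.81 at week 7. Those of Lyc2 were 2.18 and 0.654, then 1.44 and 6.13. The more abundant lysozyme gene Lyz2 was called higher at both weeks (sham to 5/6Nx, 124 to 197 and 118 to 608 FPKM). The microRNA locus differed between weeks 4 and 5 by -9.36 ± 1.63 (adjusted p = 3.85e-04). In all, 21 differences between pairs of weeks passed: 1 between weeks 2 and 4, 4 between 2 and 5, 2 between 2 and 7, 3 between 4 and 5, 5 between 4 and 7 and 6 between 5 and 7. Of these 21, 1 is not described here.

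Among the genes fixed in advance, Pdk4 differed between weeks 4 and 5 (1.33 ± 0.29, adjusted p = 0.0307). The difference of Nppa between weeks 2 and 7 (2.10 ± 0.63, adjusted p = 0.308) and that of Postn (2.94 ± 0.88, adjusted p = 0.297) did not pass, nor did Timp1 between weeks 4 and 7 (2.35 ± 0.72, adjusted p = 0.333). Where p was at its smallest deposited value the derived standard error is an upper bound, so this test is a cautious one for such loci. That does not hold where p was larger in both weeks, as for Lyc2 at weeks 5 and 7. Week 7 stood apart from the other weeks in Q30 in both surgeries, and sequencing runs were not given in the sources used here. Without week 7, 7 differences passed among the remaining pairs of weeks, and with the column names of week 7 exchanged 788 would pass. Of the 12 differences with week 7 described here, among them those of Cebpa and Lyc2, 0 would pass in that case.

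Mapping rates were compared between surgeries. They ranged from 94.0% to 94.9%, with a mean of 94.6% ± 0.21 (SD, n = 8) in 5/6Nx and 94.5% ± 0.245 (SD, n = 8) in sham libraries. The difference of 0.0875 percentage points gave p = 0.241 in the exact two-sided permutation test within weeks. Reads differed by -3.33 M (5/6Nx less sham, exact permutation p = 0.461; 1.02 M without week 7, p = 0.75) and Q30 by 0.0125 percentage points (exact permutation p = 1). Q30 was 93.2% to 94.5% at weeks 2, 4 and 5 and 96.0% to 96.2% at week 7 in both surgeries.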

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

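The test of differences in this part was planned, and the case of exchanged column names at week 7 was chosen after the results were seen. Each result below is a log2 fold change (5/6Nx over sham) that differed between 2 weeks in the z test on derived standard errors, adjusted over all loci and pairs of weeks. Differences are the later week less the earlier one. Of the 21 that passed, 1 is not described here. Of those described, 12 involve week 7, whose directions rest on its column names. With the names exchanged, 0 of these 12 would pass the z test (smallest adjusted p = 0.0582). Of the loci called at week 7, 191 of 226 had the same direction at week 2 (highest random count 146). With the names exchanged it would be 35 of 226 (lowest random count 86). These counts argue against an exchange but do not exclude it.

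S100a9 differed by 3.33 ± 0.58 between weeks 2 and 5 and by -2.47 ± 0.55 between weeks 5 and 7 (-0.95 with the names exchanged). Its partner S100a8 differed by 3.6 ± 0.77 between weeks 2 and 5, from -1.49 ± 0.39 to 2.11 ± 0.66. Sham S100a9 was 45.5, 5.62 and 39.7 FPKM in the tables of weeks 2, 5 and 7, and 5/6Nx S100a9 14.8, 18.4 and 23.5. From week 2 to 5, S100a8 went from 38.3 to 2.81 FPKM in sham and from 13.6 to 12.1 in 5/6Nx. Lyc2 differed by -2.98 ± 0.68 between weeks 2 and 5 and by 3.83 ± 0.77 between weeks 5 and 7 (exchanged -0.35). Cebpa differed by 2.87 ± 0.60 between weeks 5 and 7 (exchanged -0.92), and Cebpb by -1.37 ± 0.29 between weeks 2 and 4.

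Between weeks 4 and 7, Egr1 differed by 1.56 ± 0.34 (exchanged -0.72), Atf3 by 2.24 ± 0.50 (0.57), Apold1 by 1.54 ± 0.34 (-0.90) and Thbs1, which encodes thrombospondin 1, by 2.68 ± 0.59 (-1.90). Thbs1 also differed by 2.60 ± 0.59 between weeks 2 and 7 (-1.99). The metallothionein gene Mt2A differed by 4.26 ± 0.96 between weeks 2 and 7 (exchanged -3.28) and by 4.25 ± 0.97 between weeks 5 and 7 (-3.29), and Mt1a by 3.43 ± 0.78 between weeks 5 and 7 (-2.66). Sham Mt2A was 72.5, 26.6 and 7.98 FPKM at weeks 2, 5 and 7, and 5/6Nx Mt2A 51.5, 19.0 and 109. From week 5 to 7, Mt1a went from 74.0 to 6.93 FPKM in sham and from 56.5 to 57.2 in 5/6Nx. From week 4 to 7, sham went from 34.7 to 12.1 for Apold1 and 16.6 to 4.54 for Atf3. Sham Egr1 went from 30.4 to 6.25 and sham Thbs1 from 23.5 to 11.6. In 5/6Nx these genes went from 27.8 to 28.3, 6.25 to 8.09, 22.8 to 13.8 and 17.9 to 57.0 in this order. A common scaling of these weeks was not given in the sources used here. A difference can thus lie in sham, in 5/6Nx or in both.

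Pdk4 differed by 1.33 ± 0.29 between weeks 4 and 5, with sham at 467 FPKM at week 4 and 44.8 FPKM at week 5. Its 5/6Nx levels were 282 and 67.9 FPKM. Cdh26, a cadherin gene, differed by -1.62 ± 0.35 between weeks 4 and 5. An unnamed locus on chromosome 13 (XLOC_006702, 86863011 to 86886621) differed by 1.38 ± 0.29 between weeks 2 and 5. The Mir199a,Mir214 locus differed by -9.36 ± 1.63 between weeks 4 and 5 and by 6.07 ± 1.32 between weeks 5 and 7 (exchanged 3.59), and its length of 475.94 kb leaves open which transcript was measured.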

How the results depend on the processing

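Leaving out week 7, exchanging its column names, and leaving out each library for the mapping rate were chosen after seeing the data; the other alternatives were planned. No paired analysis was possible because the tables give 1 value per group, not per library. For the same reason no library could be left out of the gene calls, including pool 2 of the 5/6Nx group at week 7 (23.6 M reads), and no fit with a replicate block was run. The counts of calls moved with the threshold. At a q of 0.01 there were 0 calls at week 4, 0 at week 5, 137 at week 7 and 0 loci shared by at least 2 weeks. At a q of 0.10 there were 18 at week 2, 75 at week 4 and 58 shared loci. Adjustment over loci with an FPKM of at least 1 gave 14 calls at week 2, a smaller set to adjust over. An absolute log2 fold change of at least 1 left 21 calls at week 4. Without week 7 there were 12 shared loci and 7 differences between weeks, because fewer pairs of weeks were compared. With the column names of week 7 exchanged there were 12 shared loci and 788 differences, and the mean correlation was -0.024, since every direction of that week then turns. In 62 further settings these counts and values stayed close to the main ones or on the same side of the threshold. The mean correlation between weeks was 0.263 and otherwise ranged from 0.233 to 0.318, within which r of weeks 2 and 5 went from 0.22 to 0.106 with no FPKM minimum and a pseudocount of 1 (cause not tested). Of the list medians and named genes, 823 alternatives kept direction and side of the threshold, 12 crossed to outside the central 95%, 8 crossed to within it and 0 reversed; the cause was not tested. Without 1 library at a time, the difference in mapping rate ranged from 0.0161 to 0.130 percentage points. At week 7, with 68.1 M reads in 5/6Nx against 101 M in sham, the median derived standard error was 0.35, against 0.23, 0.20 and 0.22 at weeks 2, 4 and 5; an effect of depth was not tested.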

Other observations

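The tests of explanations in this part (fat tissue, atrial tissue, scaling, blood, cardiomyocyte share and direction at week 2) were all chosen after the results were seen.

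Sham levels of several clock and fuel genes differed between the tables of different weeks, for which a common scaling was not given in the sources used here. Dbp had 61.9, 67.4, 153 and 21.3 FPKM in sham at weeks 2, 4, 5 and 7, and Nr1d1, another clock gene, 34.9, 39.5, 68.0 and 7.65. Thrsp had 5.07, 6.62, 40.5 and 0.937, and Ppara 12.2, 11.2, 2.27 and 15.8. The collection hour was not given in the sources used here, and no explanation of these levels was tested.

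Of the loci called at week 5 and tested at week 2, 66 of 70 had the same direction at week 2, before any locus was called (random draws had a mean of 39.1 and a highest count of 55). Of those called at week 7 it was 191 of 226, against a mean of 115 and a highest count of 146 in random draws. With the column names of week 7 exchanged, it would be 35 of 226, against a mean of 111 and a lowest count of 86. Of those called at week 4 it was 33 of 42, at percentile 98.6 of random draws (mean 26.2, highest count 37). The changes of week 5 may thus have begun by week 2, as a hypothesis, since 66 of 70 was found and tested on the same data and 191 of 226 rests on the column names.

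Adipocyte markers were lower at weeks 4 and 5. The fall was not limited to Thrsp and Pck1, since the other markers had a median of -1.06 at week 4 and -1.69 at week 5. These markers are part of the pattern itself. They are thus no independent test of lower lipid synthesis in an unchanged amount of fat. Less fat tissue in the 5/6Nx pieces stays open, untested, since the count of 10 of 10 markers below sham at both weeks restates the pattern. Whether the animals had less fat, the 5/6Nx pieces were taken with less of it or the sham pieces with more also remains open. Thrsp had 5.07, 6.62 and 40.5 FPKM in sham and 2.51, 2.44 and 2.19 in 5/6Nx at weeks 2, 4 and 5. Adipoq had 7.10, 9.34 and 9.59 FPKM in sham and 5.97, 3.41 and 2.73 in 5/6Nx. A common scaling of these weeks was not given in the sources used here.

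Nppa was higher at weeks 5 and 7. More atrial tissue is argued against by Myl7, Myl4, Sln and Bmp10, whose weighted mean log2 fold change was 0.10 ± 0.14 at week 5 and -1.40 ± 0.21 at week 7. These lay below Nppa by 0.98 ± 0.30 and 3.85 ± 0.64. Each ± here treats the genes as independent, although all were measured in the same pools, so it may misstate the spread. The median over loci with an FPKM of at least 1 was 0.0015 at week 5 and -0.012 at week 7, so most loci did not rise with Nppa. Since the deposited abundances were already scaled, this median cannot decide on a shift in scaling. A response of the ventricle to 5/6Nx, consistent with these values, stays open as a hypothesis.

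Macrophage markers were higher at week 7 by the column names of that table, with a median of 1.18. Lymphocyte, neutrophil and mast cell markers did not rise alongside, with a median of -0.26 over 14 genes. Their upper quartile was 0.08, against a lower quartile of 0.85 for macrophage markers. The red cell list nevertheless had a median of 0.83, with 8 of 9 genes above sham, so more blood in the pieces stays open. A lower share of cardiomyocytes that raised all other cells alike is argued against by endothelial and smooth muscle markers. Their median was 0.029 over 29 genes (upper quartile 0.15). A share lost to macrophages alone could not be excluded, since these markers would then stay near 0. The sarcomere list had a median of -0.31, below random lists, with 13 of 16 genes below sham. More macrophages, or more of these transcripts per macrophage, could each account for the rise. No test here told these apart, or set them apart from more blood or a lower share of cardiomyocytes.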
